A study of Mus musculus with 4 samples.

How the data were processed

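RNA was sequenced from cultured bone marrow progenitors of 4 mice, 2 Cre control and 2 Trim33 CKO. Per the labels' protocols, RNA was purified on spin columns, and a low-input full-length cDNA kit was followed by transposon-based library preparation. Such kits do not mark the strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The authors deposited raw counts, whole numbers per gene symbol and library, with 27678 gene rows. Per the submitters' processing notes, Trimmomatic, STAR, featureCounts and the genome build mm10 were used. Their versions and options and the gene annotation are not given in the sources used here. PCR copies were not marked by molecular identifiers, so count floors and the bounds built on them cover counting error only.

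Columns were tied to mice through the sample labels. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with default settings, which left 14483 of the 17683 genes with any count. Library sizes were scaled by TMM (trimmed mean of M values), with factors of 1.05 and 1.04 for the controls and 0.948 and 0.961 for the CKO libraries. Dispersions were estimated robustly, and the quasi-likelihood model (legacy setting, the default of that version) was fitted with genotype as its single term. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to be called, or to have risen or fallen. Every adjusted p of a gene is from this edgeR test unless another tool is named, and every adjusted p of a list is from camera unless fry is named. Normalised CPM are counts scaled by the TMM-adjusted library size, given as mean ± SD over 2 mice, and fold changes are fitted values. A gene at 0 counts in a genotype has no finite fold, so a lower bound was computed against a floor of 3 counts over both libraries of that genotype. The CKO libraries were shallower than the controls: 3 counts in a single library equal 0.0311 and 0.031 normalised CPM in the controls and 0.0399 and 0.0443 in the CKO libraries.

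Before the data were examined, 35 gene lists and 20 key genes were fixed, together with the tests and the alternatives except where stated. The lists cover dendritic cell subsets, other blood lineages, stromal cells, signalling, cell cycle, stress and metabolism, with the chromosomal neighbours of Trim33 and sex-linked genes as checks. Of these, 34 had at least 5 tested members and entered camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 34 lists. With a correlation estimated from the 4 libraries no list was called (0 at an adjusted p under 0.05; smallest adjusted p = 0.162). Named genes were the key genes, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 10 CPM on library totals, before TMM scaling, in the higher genotype and no overlap between genotypes (names of predicted genes left out), and for each list up to 4 called members with the smallest adjusted p, or the member with the smallest p where none was called. This gave 123 genes, of which the text gives the main ones, and some are not reported here. On normalised CPM the same rule would take St6galnac2 and Fn1 in place of Ccl12 and Hepacam2. Nfkb1, Mrc1, Runx2, Casp6, Ifnb1 and the further genes of the closing section were chosen after their values were seen.

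Alternatives were DESeq2 1.42.0, limma-voom, the non-legacy quasi-likelihood fit, DESeq2-style size factors (RLE), library totals alone, no filter on low counts, a stricter filter (5 CPM in at least 2 libraries), the replicate number as a block, each library left out in turn, other thresholds, and for lists an estimated correlation and fry, which tests whether the genes of a list move, on balance, one way. DESeq2 was not run on the lists. With a library left out, its genotype has 1 mouse, which is then assumed to vary like those of the other genotype. Coordinates and transcript types are from GENCODE release M21 on GRCm38, the assembly also called mm10, matched by symbol. Symbols with more than 1 entry were not placed, except where stated. Where a call is said to be lost, the adjusted p given are those of the alternatives that lost it, and it stayed under 0.05 in the others that could be run, aside from the replicate block and, for lists, the estimated correlation and fry. For each list called by camera, the adjusted p with an estimated correlation is printed, and that of fry where it lost the call.

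The steps were tested on counts simulated from the means, dispersions and library sizes of the 14483 genes, with 200 genes of at least 10 CPM changed. The edgeR test called 83% of genes changed 2-fold and 100% of those changed 4-fold, with a median error of 0.132 in the log2 fold change. Of its calls 12% were unchanged genes, against 10% for limma-voom and 20.8% for DESeq2, so in this simulation each tool passed more unchanged genes than the nominal 5%. Camera called the 1 changed list and 0 of 34 unchanged lists. Genes were simulated independently of each other, so this does not test camera on lists of correlated genes. In the data the estimated inter-gene correlations ranged from -0.10 (stromal and endothelial list) to 0.59 (plasmacytoid list). Figures were drawn with matplotlib 3.10.9.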

Results

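Gene expression was measured by RNA sequencing in dendritic cell progenitors from mouse bone marrow, with and without induced loss of Trim33, a tripartite-motif E3 ubiquitin ligase and transcriptional cofactor. Flt3-positive progenitors lacking lineage markers came from 2 mice per genotype, and each mouse was kept apart. All cells were grown in Flt3 ligand, the cytokine that drives dendritic cell development, and were exposed for 3 days to 4-hydroxytamoxifen, which activates the CreER recombinase. The Cre control mice carried CreER at the Rosa26 locus. The Trim33 CKO (conditional knockout) mice carried it together with floxed Trim33 alleles. Gene counts summed to 91592191 and 92823650 in the control libraries and to 79251466 and 70572439 in the CKO libraries, and between 15627 and 15675 genes had a count in each library. The design gives 1 comparison, Trim33 CKO against Cre control, which asks how the loss of Trim33 alters the transcriptome of progenitors on the dendritic cell path.

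Trim33 itself (chromosome 3, 103279293 to 103358775, plus strand, GRCm38, also called mm10) had 20.3 ± 6.18 normalised CPM (counts scaled to library size) in the controls and 7.46 ± 1.97 in the CKO libraries (SD, n = 2 each). Both CKO libraries lay below both control libraries, with 1537 and 2382 counts in the controls and 665 and 411 in the CKO libraries. The log2 fold change was -1.44 (SE 0.31), and edgeR's adjusted p of 0.0504 fell just outside the threshold of 0.05. Its family members Trim24 and Trim28 and the TGF-beta pathway gene Smad4 had log2 fold changes of -0.39 (SE 0.27), -0.12 (SE 0.12) and -0.28 (SE 0.14), none past the threshold. Counts cover the whole gene, so reads from exons outside the floxed segment would remain in them. Such counts therefore do not measure how complete the deletion was. The adjusted p of Trim33 ranged from 0.000653 with DESeq2 to 0.285 without Cre control replicate 2 (log2 fold change -1.09), and it passed the threshold in 5 alternatives that keep all libraries and without Cre control replicate 1 (0.0378).

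Loss of Trim33 went with more increases than decreases. Of 14483 tested genes, 703 were higher and 213 lower in the CKO cells (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the increases, 579 were at least 2-fold and 207 at least 8-fold, whereas 106 of the decreases were at least 2-fold and 18 at least 8-fold. Scaling to library totals alone moved the median log2 fold change of all tested genes from -0.01 to -0.14 and gave 643 higher and 408 lower genes, so that 61.2% of calls were higher, against 76.7%. Without Cre control replicate 1 the counts were 421 and 50, without Cre control replicate 2 they were 450 and 54, and without Trim33 CKO replicate 1 there were 323 lower genes.

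**Figure D1:**
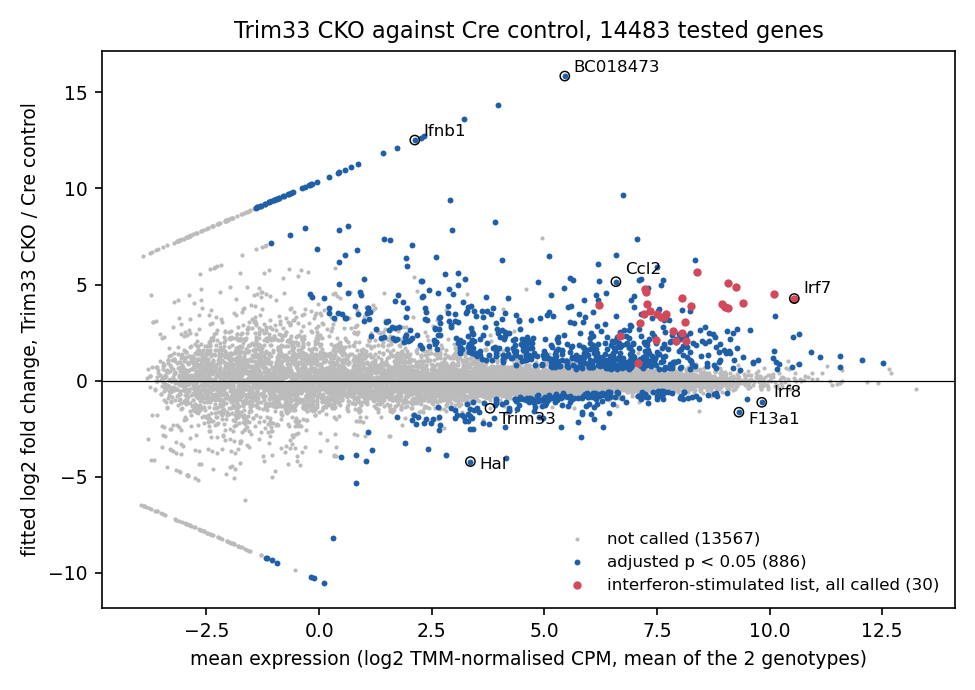
Fitted log2 fold change (vertical axis, Trim33 CKO over Cre control) against mean expression (horizontal axis, log2 of normalised CPM averaged over both genotypes), 1 point per tested gene, with the 30 listed interferon-stimulated genes in red, other called genes in blue and named genes circled. The 703 increases reach further from 0 than the 213 decreases, and the outer diagonals are genes at 0 counts in a genotype, whose fitted folds depend on the prior count.

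Several genes went from no counts to high counts. BC018473, annotated as an antisense transcript (chromosome 11, 116752167 to 116759373, plus strand), had 0 counts in both control libraries and 6920 and 5633 in the CKO libraries, at least 5658-fold higher against a floor of 3 counts over the control libraries. Hsd17b6, a hydroxysteroid dehydrogenase (chromosome 10, 127990936 to 128007611, minus strand), and Cnpy1 (chromosome 5, 28200819 to 28245806, minus strand) were likewise at 0 in the controls and were at least 2045-fold and 1206-fold higher. Without a Cre control library, when the floor rests on 1 library, the bounds of BC018473, Hsd17b6 and Cnpy1 were 2828-fold, 1023-fold and 603-fold, and that of Hsd17b6 was 1300-fold without Trim33 CKO replicate 1. Slfn4, a schlafen-family gene, rose from 0.269 ± 0.0878 to 216 ± 18.6 CPM, and Flrt3, a leucine-rich repeat transmembrane protein, from 1.59 ± 0.476 to 266 ± 13.9 CPM (SD, n = 2). Selenbp2 and Apol9a rose by 8.23 (SE 0.75) and 9.39 (SE 0.77) on the log2 scale, and the chemokine genes Ccl7 and Ccl12 by 6.52 (SE 0.47) and 6.46 (SE 0.48). Gzmc, a granzyme, rested mainly on 1 library, with 2179 and 130 counts in the CKO libraries (edgeR adjusted p = 0.0499), and its call was lost with limma-voom, with DESeq2-style size factors, without the filter on low counts, and without either Cre control library or Trim33 CKO replicate 1 (adjusted p from 0.0526 to 0.746). Its log2 fold change was 7.81, and from 4.80 without Trim33 CKO replicate 1 to 13.27 without Cre control replicate 2 (8.72 without Trim33 CKO replicate 2). Apol9a, Slfn4, Selenbp2, Ccl7 and Ccl12 have close paralogs that can share reads, so these levels are uncertain. Flrt3 overlaps Macrod2 on the other strand, and reads of the 2 strands cannot be told apart, so its level is uncertain too. The other genes named above overlap no annotated gene. Leaving out a control library put Apol9a at 13.22 or 8.45 and Selenbp2 at 7.31 or 11.30 (replicates 1 and 2), and leaving out Trim33 CKO replicate 1 put Ccl7 at 5.76 and Ccl12 at 5.74. The call of Ccl7 was lost without either Cre control library (edgeR adjusted p = 0.0589 and 0.0607).

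Steep decreases were seen in Hal, which encodes histidine ammonia-lyase, and Hpgd, which encodes the enzyme that inactivates prostaglandins. Hal (chromosome 10, 93488768 to 93519304, plus strand) fell 18.5-fold, from 19.5 ± 6.04 to 1.05 ± 0.0627 CPM, and Hpgd 16.1-fold, from 33.4 ± 7.49 to 2.07 ± 0.543 CPM (SD, n = 2; edgeR adjusted p = 0.00127 and 0.000978). Hepacam2 had a log2 fold change of -3.58 (SE 0.39). The adhesion receptor gene Adgrg5 fell from 98.7 ± 6.69 to 13.1 ± 7.65 CPM, and Pros1, which encodes anticoagulant protein S, fell 5.3-fold from 69.1 ± 12.1 CPM. Stxbp6, Abca9, Mgst2 and Rab11fip4 were lower by 5.34-fold to 5.85-fold. The call of Adgrg5 was lost without either Cre control library (edgeR adjusted p = 0.0927 and 0.0868), and that of Stxbp6 without Cre control replicate 2 or Trim33 CKO replicate 2 (0.0513 to 0.0674). The log2 fold change of Adgrg5 was -3.68 without Trim33 CKO replicate 1, against -2.91 with all libraries.

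Interferon-stimulated genes rose as a block. All 30 members of the list were higher in the CKO cells, over all tested genes and adjusted over the list alone, with a median log2 fold change of 3.70. Isg15, a ubiquitin-like modifier (chromosome 4, 156199424 to 156200818, minus strand), went from 11.9 ± 1.93 to 294 ± 4.94 CPM. Zbp1, a sensor of Z-form nucleic acid, rose 16.1-fold, Xaf1 12.3-fold, and the antiviral gene Oasl2 from 69 ± 3.63 to 967 ± 137 CPM (SD, n = 2; edgeR adjusted p from 0.000122 to 0.000175 for these genes). Irf7, a transcription factor that amplifies the interferon response (chromosome 7, 141262706 to 141266481, minus strand), reached 2846 ± 613 CPM from 148 ± 0.512. Camera called the list higher with its preset correlation (adjusted p = 1.52e-217; adjusted p = 0.162 with an estimated correlation). Without either Cre control library, 29 of the 30 genes were called.

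Genes of inflammation and NF-kB signalling were higher as a list. Of 35 tested members, 15 rose, 1 fell and 19 were not called, and 23 rose and 1 fell when adjusted over the list alone. The monocyte chemoattractant gene Ccl2 (chromosome 11, 82035571 to 82037453, plus strand) rose 35.4-fold, from 5.28 ± 0.138 to 187 ± 60.1 CPM. Il1rn, the interleukin-1 receptor antagonist, rose 12.1-fold, and the costimulatory receptor gene Cd40 3.63-fold. Whether these increases are separate from the interferon response was not tested. Il1b was at 65.5 ± 1.59 and 115 ± 32.6 CPM and did not pass the test (edgeR adjusted p = 0.0832; from 0.00345 to 0.275 over alternatives, passing with DESeq2, with the stricter filter and, at 0.0105, without Trim33 CKO replicate 2). The member that fell was Nfkb1, which encodes an NF-kB subunit, at -0.79 (SE 0.12) on the log2 scale, chosen after its values were seen. The median of the list was 1.54 (0.82 without Trim33 CKO replicate 2), and camera called it higher (adjusted p = 1.54e-17; adjusted p = 0.162 with an estimated correlation). The call of Nfkb1 was lost without either Cre control library (adjusted p = 0.0975 and 0.141).

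Macrophage genes were also higher as a list, with 17 of 35 tested members up, 1 down and 17 not called (23 up and 3 down adjusted over the list alone) and a median log2 fold change of 1.22. Fcgr1, the high-affinity IgG receptor (chromosome 3, 96282909 to 96293969, minus strand), rose 18.5-fold from 12.5 ± 1.43 CPM (SD, n = 2; edgeR adjusted p = 0.000122). The complement genes C1qc and C1qb rose 3.86-fold and 3.46-fold, and Axl, a receptor tyrosine kinase that recognises apoptotic cells, 4.96-fold. These increases were not tested apart from the interferon response either. The member that fell, chosen after its values were seen, was the mannose receptor gene Mrc1, at -2.30 (SE 0.31) on the log2 scale. Csf1r, the receptor for macrophage colony-stimulating factor, was at 965 ± 45.8 and 807 ± 291 CPM and did not pass the test, though it did without Trim33 CKO replicate 2 (log2 fold change -0.68, against 0.07 without Trim33 CKO replicate 1; adjusted p = 0.0302, in a range from 0.0302 to 0.938 over alternatives). Camera called the list higher (adjusted p = 4.26e-17; adjusted p = 0.424 with an estimated correlation and 0.118 with fry). The median member was 0.56 log2 units higher in CKO replicate 2 than in CKO replicate 1, against 0.15 between the control replicates.

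Lysosomal genes were likewise higher as a list, with 9 of 37 members higher and 28 not called, and 16 higher and 1 lower adjusted over the list alone. Gla and Ctsl, an alpha-galactosidase and a cathepsin, rose 3.28-fold and 3.69-fold, and Ctsb, another cathepsin, from 2705 ± 171 to 5748 ± 805 CPM. Ctsl and Ctsb stand in the macrophage list too. Camera called the list higher (adjusted p = 0.000196; adjusted p = 0.629 with an estimated correlation and 0.212 with fry). The call of Ctsb was lost without either Cre control library (adjusted p = 0.15 and 0.0836).

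The monocyte list split, with 5 of 22 members higher, 6 lower and 11 not called (6 and 7 adjusted over the list alone), and camera did not call it (adjusted p = 0.754). F13a1, the coagulation factor XIII A subunit (chromosome 13, 36867178 to 37050244, minus strand), fell 3.13-fold, from 967 ± 30.4 to 309 ± 5.68 CPM. Ms4a4c and Ifi27l2a rose 5.98-fold and 8.27-fold, and Ly6c2, a Ly6C antigen gene, rose 1.97-fold. Ifi27l2a also stands in the interferon list. The call of Ly6c2 was lost without either Cre control library (adjusted p = 0.119 and 0.0641).

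**Figure D2:**
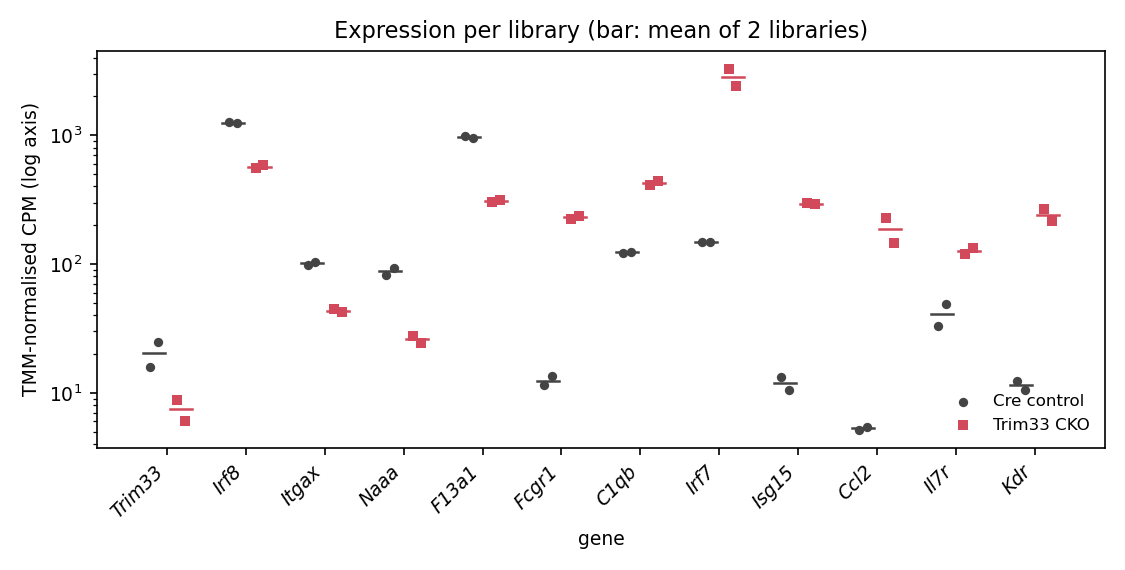
Normalised CPM (vertical log axis) of 12 of the named genes (Trim33, Irf8, Itgax, Naaa, F13a1, Fcgr1, C1qb, Irf7, Isg15, Ccl2, Il7r and Kdr) in each library, circles for the Cre control libraries and squares for the Trim33 CKO libraries, with a bar at each group's mean. The genotypes do not overlap for these 12 genes, whereas others such as Csf1r and Xcr1, not drawn, did overlap, and the adjusted p of Trim33 (0.0504) did not pass the threshold.

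Irf8, the transcription factor that specifies type 1 conventional dendritic cells (chromosome 8, 120736358 to 120756694, plus strand), was 2.19-fold lower. It went from 1245 ± 15.8 to 569 ± 21.6 CPM (SD, n = 2; edgeR adjusted p = 0.004) and kept its call in each alternative run. Within the list of dendritic cell transcription factors, 3 of 27 members fell, 2 rose and 22 were not called (5 and 2 adjusted over the list alone). Klf4 and Runx2, the latter chosen after its values were seen, fell by 1.79 (SE 0.25) and 1.32 (SE 0.21) on the log2 scale, while Relb and Gfi1 rose by 0.83 (SE 0.12) and 1.56 (SE 0.24). Cbfa2t3, which encodes the corepressor ETO2, had a log2 fold change of -0.68 (SE 0.15, edgeR adjusted p = 0.056, from 0.00327 to 0.336 over alternatives, passing with DESeq2, the non-legacy fit, library totals and the stricter filter). Batf3 was at -0.82 (SE 0.35), Zbtb46 at -0.77 (SE 0.28), Irf4 at -0.85 (SE 0.55) and Tcf4 at -0.37 (SE 0.12), and Id2, Zeb2, Spi1 and Bcl11a lay between -0.12 and 0.22, none past the threshold. Irf4 was at -1.85 without Trim33 CKO replicate 1 and -0.27 without Trim33 CKO replicate 2. Camera called the list lower (adjusted p = 0.0383; adjusted p = 0.424 with an estimated correlation and 0.0994 with fry), and the call was lost with a stricter filter on low counts (0.0646), without Cre control replicate 2 (0.0811) and without either CKO library (0.0725 and 0.116). The calls of Klf4, Relb and Gfi1 were lost without either Cre control library (adjusted p from 0.0553 to 0.129).

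Markers of type 2 conventional dendritic cells were lower as a list, with a median log2 fold change of -0.97 (-0.63 without Cre control replicate 2). Of 14 members, 3 fell and 11 were not called, and 7 fell and 1 rose adjusted over the list alone. Cd209d, a C-type lectin, went from 3.93 ± 0.125 to 0.214 ± 0.114 CPM, a log2 fold change of -4.19 (-4.87 without Trim33 CKO replicate 2). Cd7 went from 86.1 ± 9.82 to 27.6 ± 14.7 CPM, and the transcription factor gene Klf4 was the third member to fall. Camera called the list lower (adjusted p = 0.00847; adjusted p = 0.424 with an estimated correlation), and the call was lost with the stricter filter (0.0646). The call of Cd7 was lost with that filter and with DESeq2-style size factors (0.0514 and 0.0532), and those of Cd7 and Klf4 without either Cre control library (adjusted p from 0.0553 to 0.279), while the log2 fold change of Cd7 went from -1.64 to -2.32 without Trim33 CKO replicate 1.

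Markers of type 1 conventional dendritic cells and of plasmacytoid dendritic cells moved in both directions, and camera called neither list. In the type 1 list 4 of 18 members rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.629). Naaa, a lysosomal amidase, fell 3.36-fold, from 87.7 ± 7.6 to 26.1 ± 2.22 CPM, whereas Ifi205, an interferon-inducible gene, rose 6.28-fold. The chemokine receptor gene Xcr1 was at 26 ± 1.22 and 25.4 ± 15.5 CPM, and its log2 fold change of -0.04 was -0.85 without Trim33 CKO replicate 1 and 0.48 without Trim33 CKO replicate 2, none past the threshold. In the plasmacytoid list 5 of 21 members rose and 3 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.587). Its risers included Irf7 and Bst2, which also belong to the interferon list, and Tlr7, a sensor of single-stranded RNA that rose 3.16-fold. The type 1 list had a median of -0.06, a mean of 0.08 and a downward test, and the plasmacytoid list a median of -0.38, a mean of 0.01 and an upward test. Siglech, a marker of plasmacytoid cells, was at 139 ± 28.6 and 55.2 ± 39.5 CPM and did not pass the test (edgeR adjusted p = 0.19). Without Trim33 CKO replicate 1, Siglech was lower (log2 fold change -2.35, against -0.74 without Trim33 CKO replicate 2; adjusted p = 0.0083, in a range from 0.0083 to 0.801 over alternatives) and the plasmacytoid list was called lower (median -0.86, camera adjusted p = 0.0348).

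In the conventional dendritic cell core 4 of 25 members rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.977). Ccr7, the lymph-node homing receptor, and Traf1 rose 3.28-fold and 2.52-fold, while Itgax, which encodes CD11c, fell 2.33-fold to 43.5 ± 1.56 CPM. Flt3, the receptor on which the cells were sorted, was at 463 ± 12.3 and 386 ± 55.8 CPM, a difference that did not pass the test (edgeR adjusted p = 0.388). In the antigen presentation list 3 of 16 members rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.977). The costimulatory Cd40 and the protease gene Ctss were higher, and the peptide-loading genes H2-DMb1 and H2-DMa were 1.74-fold and 1.58-fold lower. The core list had a median of 0.02, a mean of 0.09 and a downward test, and the antigen presentation list a median of -0.12, a mean of 0.15 and a downward test. The calls of H2-DMb1 and H2-DMa were lost without either Cre control library (adjusted p from 0.0802 to 0.283), and that of Ctss without Cre control replicate 1 (0.156).

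Lists of progenitors and other lineages were called higher with few of their members called. Log2 fold changes were positive for 20 of 23 stem and multipotent progenitor, 14 of 17 B lymphoid and 14 of 17 granulocyte-monocyte progenitor members. They were positive for 12 of 13 members of the mast cell and basophil list and 3 of 7 of the stromal and endothelial list. In the stem and multipotent progenitor list 2 of 23 rose (4 adjusted over the list alone; camera adjusted p = 0.0132, and adjusted p = 0.424 with an estimated correlation). These were Ly6a, the stem cell antigen Sca-1, which interferon also induces, from 199 ± 34.3 to 2032 ± 1057 CPM, and Hoxa9, by 0.79 (SE 0.15) on the log2 scale. In the B lymphoid list 2 of 17 rose (5 adjusted over the list alone; camera adjusted p = 0.0407, and adjusted p = 0.424 with an estimated correlation and 0.0852 with fry), the interleukin-7 receptor gene Il7r 3.12-fold and the adaptor gene Blnk 1.67-fold. In the granulocyte-monocyte progenitor list 2 of 17 rose, Gfi1 and Ms4a3 (5 adjusted over the list alone; camera adjusted p = 0.0326, and adjusted p = 0.463 with an estimated correlation and 0.0994 with fry). The B lymphoid call was lost with the stricter filter and without Trim33 CKO replicate 1 (0.274 and 0.0813), and the granulocyte-monocyte call on library totals and with the stricter filter (0.0517 and 0.0634). Gfi1 and Ms4a3 lost their calls without either Cre control library (adjusted p from 0.0745 to 0.198), Hoxa9 and Blnk on library totals (0.0516 and 0.0645) and without any of the 4 libraries (0.0513 to 0.343), and Ly6a without Cre control replicate 1 (0.0525; log2 fold change 2.69 without Trim33 CKO replicate 1, against 3.35).

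In the mast cell and basophil list 3 of 13 rose, and 7 adjusted over the list alone (camera adjusted p = 0.00271, and adjusted p = 0.424 with an estimated correlation and 0.0921 with fry). They were Csf1, which encodes macrophage colony-stimulating factor, at 3.9 ± 0.438 and 17.1 ± 5.76 CPM, the steroid synthesis gene Cyp11a1, with 3 and 46 counts in the controls and 632 and 702 in the CKO libraries, and the IgE receptor gene Fcer1a. Fcer1a was at 0 counts in the controls and 66 and 50 in the CKO libraries, at least 52.3-fold higher (26.1-fold without a Cre control library). In the stromal and endothelial list Kdr, which encodes a vascular endothelial growth factor receptor (chromosome 5, 75932827 to 75978458, minus strand), was the 1 of 7 members to rise, from 11.5 ± 1.28 to 242 ± 38 CPM, and 2 rose adjusted over the list alone. The median of that list was -0.01, also with its member at 0 counts in a genotype set at its bound, while its mean and its camera call were positive (adjusted p = 0.00847, and adjusted p = 0.424 with an estimated correlation). The stromal call was lost with limma-voom and without any of the 4 libraries (adjusted p from 0.0811 to 0.587). Fcer1a lost its call with the non-legacy fit (0.0588) and without any of the 4 libraries (0.122 to 0.136) and Cyp11a1 without either CKO library (0.0732 and 0.0977), and the log2 fold change of Cyp11a1 was 4.29 or 8.18 without control replicate 1 or 2, against 5.20.

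The other lineage lists were not called. Mature neutrophil genes had 1 member higher and 1 lower of 17, over all genes and adjusted over the list alone (camera adjusted p = 0.963). These were the metalloproteinase genes Mmp25, at 3.76 (SE 0.51) on the log2 scale, and Mmp8, at -1.16 (SE 0.19). In the erythroid and megakaryocyte list Car2, a carbonic anhydrase, was the 1 of 15 members to rise, 1.74-fold (3 adjusted over the list alone; camera adjusted p = 0.207, and 0.0132 without Cre control replicate 2). In the T and NK list the receptor gene Klrd1 was the 1 of 14 to fall, 2.45-fold (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.977). No eosinophil gene of 6 was called by edgeR or limma-voom, 2 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 2 higher. Adjusted over the list alone, 2 were higher and 1 lower (camera adjusted p = 0.602). Epx, the eosinophil peroxidase gene, had the smallest p, with 5 and 0 counts in the controls and 179 and 41 in the CKO libraries. Among cytokine receptors Il7r rose and Il6ra and Ifnar2, the latter encoding an interferon receptor chain, fell by 0.72 (SE 0.14) and 0.59 (SE 0.12) on the log2 scale, of 24 members (2 higher and 4 lower adjusted over the list alone). That list had a median of 0.08, a mean of 0.09 and a downward test (camera adjusted p = 0.948). The calls of Car2, Il6ra and Ifnar2 were lost without either Cre control library (adjusted p from 0.107 to 0.363), those of Mmp8 and Klrd1 without Cre control replicate 2 (0.0599 and 0.114), those of Car2, Klrd1 and Il6ra without Trim33 CKO replicate 2 (0.0567 to 0.0663) and that of Il6ra without Trim33 CKO replicate 1 (0.0511). Epx passed the test with DESeq2, with the non-legacy fit and without Cre control replicate 1 (adjusted p from 0.000988 to 0.32 over alternatives, 0.048 without that library).

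Genes of the G2 and M phases were lower, with 5 of 52 members down and 47 not called, and 9 down adjusted over the list alone. Cdc25c, a phosphatase that starts mitosis, went from 52.6 ± 1.97 to 30.2 ± 0.232 CPM, and the proliferation marker Mki67 from 334 ± 30.4 to 179 ± 42.3 CPM. Cenpa, a centromeric histone, and Birc5, which encodes survivin, fell 1.53-fold and 1.49-fold. The median log2 fold change was -0.36 (-0.23 without Trim33 CKO replicate 2; camera adjusted p = 3.1e-07; adjusted p = 0.44 with an estimated correlation and 0.118 with fry). No S phase gene of 41 was called by edgeR or limma-voom, over all genes or, for edgeR, adjusted over the list alone, while 3 were lower at an unadjusted p under 0.05 and DESeq2 called 1 lower. Uhrf1, which maintains DNA methylation, had the smallest p of these, at -0.52 (SE 0.12) on the log2 scale, and passed the test with DESeq2, library totals, the stricter filter and without Trim33 CKO replicate 2 (edgeR adjusted p = 0.0485 without that library, from 0.00314 to 0.476 over alternatives). Camera did not call the S phase list (adjusted p = 0.205), except without Trim33 CKO replicate 1 (0.0247). The calls of Cdc25c, Cenpa, Mki67 and Birc5 were lost without either Cre control library (adjusted p from 0.0868 to 0.35), and that of Birc5 without Trim33 CKO replicate 2 (0.0556).

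Stress and survival genes changed in several lists. In the apoptosis list 7 of 28 members rose, 1 fell and 20 were not called (7 and 3 adjusted over the list alone; camera adjusted p = 0.0383, and adjusted p = 0.424 with an estimated correlation and 0.0949 with fry). Bcl2l11, which encodes the pro-apoptotic BIM, rose 5.03-fold, and the inflammatory caspase gene Casp4 3.54-fold. The survival genes Bcl2a1b and Bcl2l1 rose 2.91-fold and 2.92-fold, and Bcl2a1b has near-identical copies that can share its reads. The member that fell, chosen after its values were seen, was the caspase gene Casp6, at -0.85 (SE 0.15) on the log2 scale. The median of the list was 0.14, and 0.00 on library totals. Its call was lost with limma-voom, library totals and the stricter filter (adjusted p from 0.0561 to 0.0759) and without Cre control replicate 1 or either CKO library (0.123 to 0.274; medians 0.09 and 0.42 without CKO replicates 1 and 2). The call of Casp6 was lost without either Cre control library or CKO replicate 2 (0.056 to 0.22), and that of Bcl2l1 without Cre control replicate 1 or CKO replicate 2 (0.0594 to 0.0758).

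In the immediate early list 5 of 19 rose (9 adjusted over the list alone; camera adjusted p = 0.013, and adjusted p = 0.481 with an estimated correlation and 0.132 with fry), among them the stress-induced transcription factor gene Atf3, 4.94-fold, and the phosphatase gene Dusp1, 3.83-fold. In the unfolded protein and integrated stress list 3 of 23 rose, Atf3, Ddit3 and Asns (8 adjusted over the list alone; camera adjusted p = 0.0033, and adjusted p = 0.424 with an estimated correlation). Ddit3, which encodes CHOP, went from 10.1 ± 1.85 to 36.1 ± 6.93 CPM, and Asns, asparagine synthetase, from 26.8 ± 6.66 to 56.5 ± 2.01 CPM. Among p53 targets 1 of 26 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.152). Plk2, a polo-like kinase, rose 3.91-fold, and Zmat3, Ccng1 and Ercc5 fell by 1.93 (SE 0.29), 0.94 (SE 0.15) and 1.05 (SE 0.21) on the log2 scale. The immediate early call was lost without Trim33 CKO replicate 2 (0.128). The calls of Dusp1 and Ccng1 were lost without either Cre control library (adjusted p from 0.0547 to 0.107), that of Ercc5 without Cre control replicate 1 or either CKO library (0.0915 to 0.269), that of Asns without Cre control replicate 2 or either CKO library (0.0679 to 0.147), and that of Zmat3 without Cre control replicate 2 (0.0688).

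Ribosomal protein and cholesterol synthesis genes were lower as lists. Ribosomal protein genes had a median log2 fold change of -0.28 (-0.12 without Cre control replicate 1), with 2 of 77 lower (1 adjusted over the list alone), Rpsa by 1.72-fold and Rps15a by 1.89-fold. Their median member was 0.24 log2 units lower in control replicate 2 than in control replicate 1, a shift near that between genotypes, and 0.04 lower in CKO replicate 2 than in CKO replicate 1. Many have pseudogene copies, so their counts are uncertain. Camera called the list lower (adjusted p = 1.25e-05; adjusted p = 0.649 with an estimated correlation and 0.272 with fry). Cholesterol synthesis genes had a median of -0.32 and were called lower as a list (camera adjusted p = 0.0033; adjusted p = 0.625 with an estimated correlation and 0.124 with fry), yet edgeR and limma-voom called none of the 21 members, nor did edgeR when adjusted over the list alone. At an unadjusted p under 0.05, 7 were lower, and DESeq2 called 2 lower. Fdps, a synthase of the pathway with the smallest p, had a log2 fold change of -0.57 (SE 0.14) and passed the test with DESeq2 and on library totals (adjusted p from 0.0096 to 0.436 over alternatives). The call of Rpsa was lost without either Cre control library (adjusted p = 0.179 and 0.0934), and that of Rps15a without Cre control replicate 1 or either CKO library (adjusted p from 0.0683 to 0.229).

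The remaining lists were not called. In the TGF-beta and SMAD list, the pathway of Smad4, 3 of 31 members rose, over all genes and adjusted over the list alone (camera adjusted p = 0.754). They were Tgif1, a SMAD corepressor, by 0.73 (SE 0.13), Tgfbi, an extracellular matrix protein, by 0.97 (SE 0.19), and Bhlhe40, a transcription factor, by 0.76 (SE 0.16) on the log2 scale. In the transcription elongation list Ell2, an elongation factor, was the 1 of 34 to rise, 2.57-fold, also adjusted over the list alone (camera adjusted p = 0.716), and that list had a median of -0.03, a mean of 0.03 and a downward test. No glycolysis and hypoxia gene of 22 was called by edgeR, over all genes or adjusted over the list alone, while 3 were higher at an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 1. The smallest p there was that of the growth factor gene Vegfa, at 5.51 ± 1.63 and 13.3 ± 1.14 CPM, which passed the test with DESeq2, limma-voom, the non-legacy fit and the stricter filter (adjusted p from 0.00237 to 0.325 over alternatives), and the list was called higher without Trim33 CKO replicate 1 (camera adjusted p = 0.0154, against 0.754). No mitochondrially encoded gene of 15 was called by edgeR, DESeq2 or limma-voom, or had an unadjusted p under 0.05 (camera adjusted p = 0.617), and the smallest p, that of mt-Co1, was 0.0501. The calls of Tgif1, Tgfbi and Bhlhe40 were lost without either Cre control library (adjusted p from 0.0504 to 0.372), those of Tgfbi and Bhlhe40 without Trim33 CKO replicate 2 (0.077 and 0.0734) and that of Bhlhe40 without Trim33 CKO replicate 1 (0.086) and on library totals (0.0669). Under library totals alone the medians of the conventional dendritic cell core (-0.12), TGF-beta (-0.12), glycolysis (-0.08), cytokine receptor (-0.05) and sex-linked (-0.03) lists were negative, whereas they were positive with the main scaling. With 1 library left out, the medians of the type 1, conventional core, antigen presentation, mature neutrophil, stromal, TGF-beta, glycolysis, cytokine receptor and mitochondrially encoded lists each changed sign at least once.

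Among the chromosomal neighbours of Trim33, Dennd2c (chromosome 3, 103102604 to 103169769, plus strand) was the 1 of 15 to fall, 2.76-fold, also adjusted over the list alone. Camera did not call the list (adjusted p = 0.058), but did with limma-voom weights (0.0157), without the filter on low counts (0.0244), without either Cre control library (0.0146 and 0.0431) and without Trim33 CKO replicate 1 (0.00107). The call of Dennd2c was lost without either Cre control library or Trim33 CKO replicate 2 (adjusted p from 0.0527 to 0.144). Other genes named here that lie within 20 Mb of Trim33 are Csf1 (4.43 Mb away), Fcgr1 (7.03 Mb), Ctss (7.78 Mb), Selenbp2 (8.62 Mb), Il6ra (13.4 Mb) and Fdps (14.2 Mb). Cgn (8.55 Mb), BC021767 (8.65 Mb) and Tuft1 (8.68 Mb), named in the closing section, lie there too. The list of sex-linked genes had 4 tested members, too few for the list test, and none was called by edgeR, DESeq2 or limma-voom or had an unadjusted p under 0.05. Xist had 0 counts and the Y-linked Ddx3y between 6246 and 7975 counts in all 4 libraries.

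**Figure D3:**
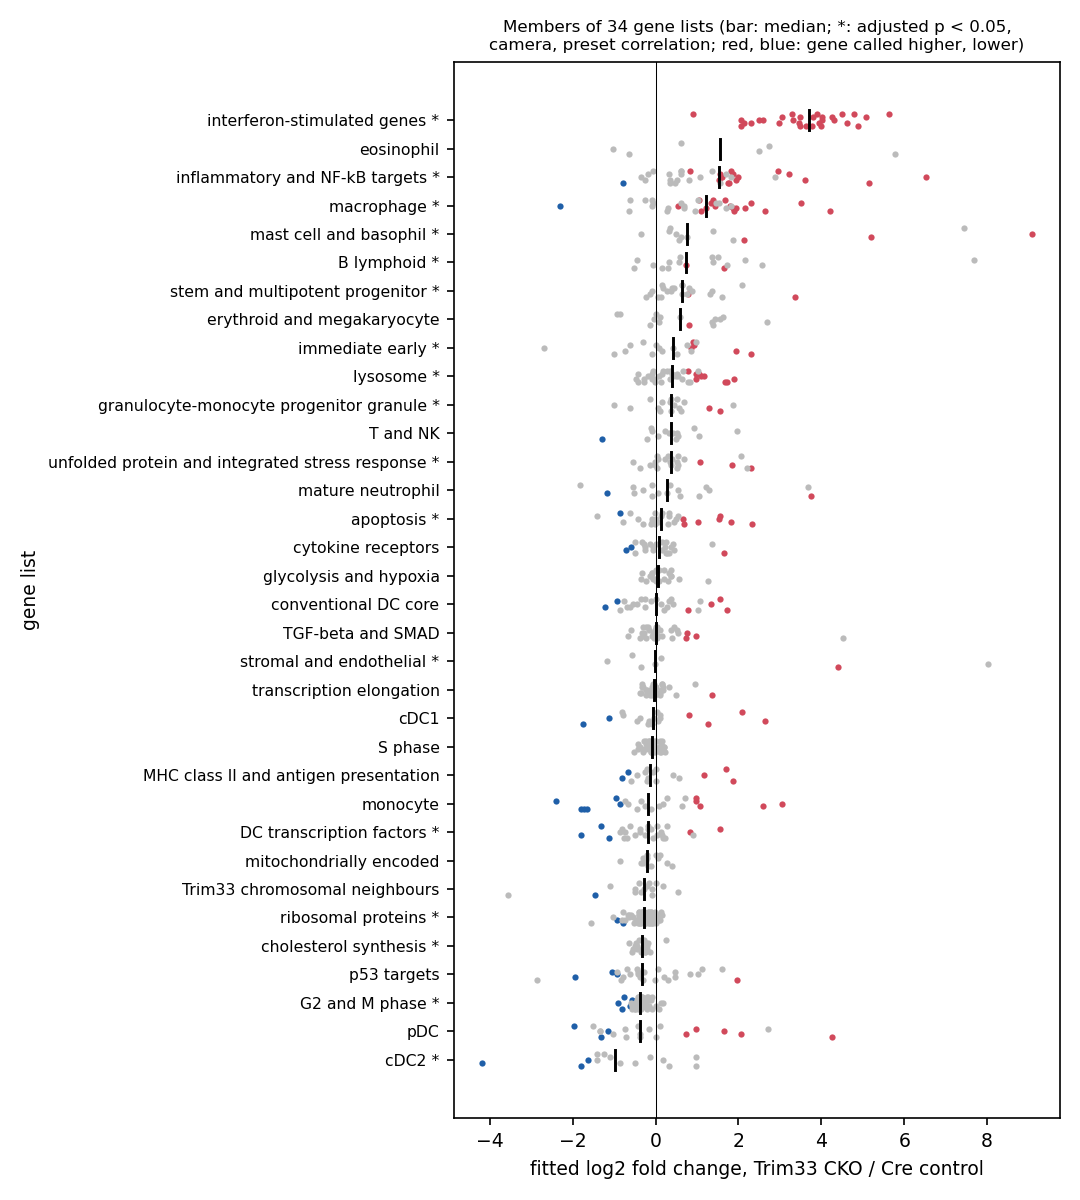
Fitted log2 fold change (horizontal axis, Trim33 CKO over Cre control) of each tested member of the 34 tested gene lists (vertical axis), with a bar at the list's median, red and blue points for genes called higher or lower, grey points for genes not called, and an asterisk for lists with a camera adjusted p under 0.05 at the preset correlation. All 30 members of the interferon-stimulated list lie above 0, around a median of 3.70, whereas the markers of type 1 and plasmacytoid dendritic cells spread to both sides.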

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

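Taking the interferon-stimulated genes out of the other lists was chosen after seeing the data, and all other alternatives were set beforehand. That removal left 12 lists higher and 5 lower. Only the plasmacytoid list (2 members) and the monocyte list (1 member) shared genes with the interferon list, and camera called neither. The outcome was thus nearly fixed in advance and does not part the called lists from the interferon response. Where no cause is stated, the cause was not tested. Of the results compared, the plasmacytoid list changed direction: its uncalled upward test became a downward call without Trim33 CKO replicate 1, and its median log2 fold change ranged from -0.86 to -0.27 with 1 library left out. Against 703 higher and 213 lower genes, DESeq2 gave 1217 and 606, which held all 703 and all 213, and library totals without TMM gave 408 lower genes. An adjusted p under 0.01 gave 313 and 31, and a 2-fold minimum gave 106 lower, as stricter thresholds must. Leaving out 1 library, with fewer samples in each fit, gave 421 to 717 higher and 50 to 323 lower genes. With the replicate block there were 661 higher and 170 lower genes and 11 and 5 lists, and the log2 fold change of Trim33 was -1.43; deviations of same-numbered libraries correlated at -0.02 across genes, so the numbers were not taken to pair the mice. For Trim33 the log2 fold change was -1.43 with DESeq2, -1.44 with the non-legacy fit, -1.58 on library totals, -1.45 without the filter and -1.43 with the stricter filter, where it passed the threshold, and -1.74 to -1.09 with 1 library left out. Against 12 lists higher and 5 lower, an estimated correlation gave 0 and 0, fry, which tests each list by itself, 5 and 1, the stricter filter 3 lower, and leaving out 1 library 9 to 12 higher and 4 to 7 lower. Of 114 called genes named here or chosen by the rule, 102 kept their call in each alternative that keeps all libraries and 63 in every alternative. Most losses came without a control library, 42 without replicate 1 and 43 without replicate 2, against 11 and 19 without a CKO library. Depth limits genes with few counts: 3 counts over a genotype is the floor for a fold.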

Other observations

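The tests below were chosen after the results were seen, except that of GC content and transcript length. Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522774, minus strand), had 0 counts in both Cre control libraries and 901 and 368 in the Trim33 CKO libraries, at least 572-fold higher (edgeR adjusted p = 0.00298). That bound was 350-fold without Trim33 CKO replicate 1 and 286-fold without a Cre control library. Of 21 interferon genes among the rows, 3 had any count, and those other than Ifnb1 had 7 counts in total over the 4 libraries. Among genes chosen after their values were seen, Tlr4, the endotoxin receptor, went from 19.2 ± 0.75 to 59.8 ± 9.45 CPM, Tlr13, a sensor of bacterial RNA, from 87.4 ± 13.5 to 205 ± 9.53 CPM, and Cgas, the sensor of cytosolic DNA, from 24.9 ± 2.32 to 49.6 ± 5.93 CPM (SD, n = 2). Of other Toll-like receptor genes, Tlr3 and Tlr7 were called higher, while Tlr1, Tlr5 and Tlr9 were tested and not called. The call of Cgas was lost without either Cre control library or Trim33 CKO replicate 1 (edgeR adjusted p from 0.0514 to 0.142).

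Some of the strongest increases lay beside each other. Within 100 kb of BC018473 on chromosome 11, St6galnac2 (2 overlapping annotation entries between 116675303 and 116694868) was at 0 counts in the controls and 747 and 694 in the CKO libraries, and St6galnac1 at 0 against 134 and 140. Near Cnpy1, the homeobox gene En2 was at 0 against 570 and 214 counts. Near Selenbp2, Tuft1 rose from 6.13 ± 2.4 to 112 ± 25.3 CPM, and Cgn was at 0 against 292 and 227 counts. Near Irf7, Sct had 1 and 11 counts in the controls and 851 and 362 in the CKO libraries. Beside the chemokine gene Ccl2, Ccl8 was at 0 against 1095 and 302 counts, a call lost with limma-voom (adjusted p = 0.0567). The call of St6galnac1 was lost without Trim33 CKO replicate 2 (edgeR adjusted p = 0.0585).

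The log2 CPM difference between libraries of a genotype had an SD across genes of 1.02 in the CKO pair and 0.88 in the control pair. The median mature neutrophil gene was 1.29 log2 units higher in CKO replicate 2 than in CKO replicate 1, against 0.40 between the control replicates. For the eosinophil list these differences were -1.14 and -0.31, for the plasmacytoid list -0.59 and 0.12, and for the macrophage list 0.56 and 0.15. The other lists differed by less than these between the CKO replicates.

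Interferon-stimulated genes rose by a median of 3.70 on the log2 scale. The tables argue against scaling between libraries, since the lowest median over 3 scalings was 3.56, and against GC content and transcript length, since the highest median among 10000 random lists matched on both was 0.53. A larger share of macrophages at a fixed level per cell stays open. The list's median exceeded that of the macrophage list by 2.47 (bootstrap 95% interval over genes, not mice, 1.92 to 3.09). Under a changed share a gene's fold also depends on its level in the other cells, so this gap cannot decide the question. A response to interferon beta made in the CKO cultures is a hypothesis that these data do not test; blocking the interferon receptor, or removing Ifnar1, in the same cultures would. Genotype cannot be parted here from litter, background or the health of 2 mice per genotype.

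A further pattern is the 23 genes with at most 3 counts in each library of a genotype and at least 100 in each of the other, 19 of them higher and 4 lower in the CKO cells. Passenger variants beside the floxed allele are argued against as the whole cause, since 9.09% of the 22 placed genes (2, Cgn and BC021767) lay within 20 Mb of Trim33, against 2.48% of other tested genes (one-sided Fisher exact p = 0.103), and 7.65% of the 353 genes there were called against 6.28% elsewhere (p = 0.174, same test). For those 2 genes, and for Csf1, Fcgr1, Ctss, Selenbp2, Tuft1 (8.68 Mb away), Il6ra and Dennd2c, which lie in the same interval, such variants stay open. Reads shared with an overlapping called gene are argued against, as 0% overlapped a gene called in the same direction. A partner outside the tested genes could not count here, so reads from such a partner stay open. Local activation of neighbours stays open: 9 of 18 placed higher genes and 37.1% of other called-higher genes had a called-higher neighbour within 100 kb (odds ratio 1.69, two-sided Fisher exact p = 0.325), against 13.3% of genes not called, and with symbols of overlapping entries such as St6galnac2 placed too, 10 of 19 did (odds ratio 1.89, p = 0.228, same test).

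The macrophage list rose by a median of 1.22 on the log2 scale, and scaling is argued against by the lowest median over 3 scalings, 1.09. Of 34 members with at least 10 CPM in the higher genotype, 23 were higher and 3 (Mrc1, Fcgr3 and Cd163) lower than control by over 2 standard errors, and these 3 passed the threshold adjusted over the list alone (edgeR adjusted p = 0.000918, 0.00945 and 0.0269). There was 1 such lower member (Mrc1) without Cre control replicate 1, there were 2 (Mrc1 and Fcgr3) without Cre control replicate 2 and 7 without Trim33 CKO replicate 2, and 2 of 29 with the level averaged over both genotypes. The number of lower members needed to argue against a larger share of macrophages (2, then 3) and the level were both changed after these values were seen, and the count did not reach 3 in each of these settings, so a larger share may account for the rise and cannot be told apart from a change within the cells. Culture followed the lineage-negative sort, so the gate would not remove macrophages formed during the 3 days.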
